A study of Mus musculus with 3 samples.

How the data were processed

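Single-cell RNA-seq of mouse tumour tissue gave 3 libraries, labelled Flox+ICI, Flox+RI and CKO+RI, each the only library of its group. The groups were taken from the sample titles. The deposited matrices hold whole-number UMI counts per gene and barcode, and the authors made them with Cell Ranger, version 6.0 per the submitters' processing notes and version 6.1.2 per the file headers. The genome build was mm10 (GRCm38) per the submitters' processing notes, which also name Seurat 5.0.3 without a step. The gene annotation behind the counts is not given in the sources used here. Each matrix covered 32285 genes, and every barcode in it held at least 500 UMIs. No normalisation had been applied to the counts. Droplet counts of this kind also hold free RNA from broken cells, and their depth per cell follows both RNA content and sequencing depth.

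Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. Doublets were then scored per library with the scrublet procedure of scanpy 1.11.5, and the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took out 915 barcodes of Flox+ICI (8.56%), 1367 of Flox+RI (10.5%) and 653 of the library labelled CKO+RI (7.23%). In all, 29866 of 33482 barcodes were kept. Depth was 75543561, 101840883 and 161250286 UMIs, in the same order. Counts per cell were scaled to 10000, log-transformed, and clustered on 2000 variable genes chosen over the per-library selections, 30 principal components and 15 neighbours with the Leiden method at resolution 1.0, without integration of the libraries, since with 1 library per group an integration could remove the comparison itself. This gave 24 clusters. A second clustering of T and NK cells gave 12 clusters (T0 to T11) and that of stromal cells gave 10 (S0 to S9).

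Clusters were named "X-like" from fixed marker lists. A cluster took the class whose markers lay highest over the median cluster, on a log2 scale with 10 CPM added, if that mean was at least 1. At least 3 of its markers had to be found in 10% of the cells, and its 10 leading genes could not hold more markers of another class. Clusters with a median depth under 1/3 of their own library's also needed a marker of the class among those genes. Clusters with Xist under 20 CPM got no host name. They were called erythroid or platelet at a score of at least 3, and otherwise tumour at a score of at least 0. Within T and NK cells the minimum was 0.5 with a lead of 0.3 over the next class, and other clusters there were called T cell-like. These scoring thresholds and the Xist limit were set after the data were seen. By these rules 5 of the first clusters and 4 of the second stayed unnamed. The names were made here and are not those of the authors.

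A share is the number of cells of a class over all kept cells of the library, with an exact binomial (Clopper-Pearson) 95% interval. For expression, the UMIs of a class were summed per library and divided by the class total, as UMIs per 1000000 (CPM), with exact Poisson intervals. Ratios between 2 libraries carry the exact conditional binomial interval. A gene at 0 in one library was set against a floor of 3 counts. The fold against this floor leaves out the counting error of the other library and is not a lower bound. Cells are not replicates, so no p-values or standard errors were made, and changed genes were not counted over all genes. The comparisons were CKO+RI against Flox+RI and Flox+RI against Flox+ICI, in classes with at least 50 cells in both libraries. Fibroblast-like cells fell under that minimum and were replaced by neutrophil-like cells.

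Genes were named by a rule of size. In each of 5 classes per comparison, the 3 genes highest in the first library and the 3 highest in the second were taken by the interval bound nearest to 1. They needed at least 50 UMIs in the higher library, a UMI in at least 10% of its cells and a level in the class at least 0.5 times that over all kept cells. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, Y-linked, Gm and Rik genes, Xist and Tsix were left out. Sfrp2 was always named. In each gene list described, members with large ratios whose interval left out 1 were named, and some that did not differ. Some list members that this would name are not reported here. For 25 gene lists, the median log2 ratio was taken over members with at least 20 UMIs in the 2 libraries together, with 0.5 counts added to each sum. Its percentile among 10000 random lists of the same size, matched on mean level in 20 bins, was used as a description. The filters, clustering settings, comparisons, markers, gene lists and the rule for named genes were fixed before the data were examined.

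The statistics were tested on Poisson counts simulated from the mean profile of the 2 libraries of a class, with 200 genes changed by 2- or 4-fold. The limits on detection and on level in the class were not part of this test. For macrophage-like cells of CKO+RI against Flox+RI (12567 genes), 95.6% of the intervals held the true ratio. Of the 50 genes ranked first, 50 were truly changed, and 12 of 200 unchanged lists fell in the outer 5% of the random lists. For CD8 T cell-like cells of the same comparison (8415 genes) the coverage was 96.4%, with 7 such lists. For Flox+RI against Flox+ICI it was 95.8% in macrophage-like cells (12792 genes), with 11 such lists, and 96.2% in CD8 T cell-like cells (7610 genes), with 9.

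Alternatives tried were at most 10% mitochondrial UMIs, at least 500 genes, no doublet removal, Leiden resolutions 0.5 and 2.0, variable genes without those that differed over 2-fold between libraries within a broad class (6482 genes), shares outside the tumour class or of leukocyte classes, thinning to 2000 UMIs per cell, TMM factors (edgeR 4.0.16), the mean over cells in place of the sum, and list members with at least 100 UMIs or with any UMI. The tumour class pooled with the Xist-low clusters 2 and 8 but without the erythroid and platelet ones, cells outside this pool as the denominator, cluster 15 counted with neutrophil-like cells, cluster 0 alone, tumour cells without cluster 3 and CD8 T cell-like or all T cell-like cells without cluster T11 were added after the data were seen, as was a check of macrophage markers in endothelial cell-like cells. Gene positions came from GENCODE vM21 (GRCm38). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3, were used, with seed 0 for clustering and random lists.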

Results

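Single-cell RNA profiles of mouse tumour tissue were compared between 3 treatment groups with 1 library each. The tumours grew from LLC1-sgLkb1 cells, a Lewis lung carcinoma line that the labels describe as carrying an LKB1 knockdown. LKB1 is a tumour suppressor kinase. In the series' design, these cells were seeded in the lung through a tail vein and, 3 weeks later, under the skin, where the tumour was irradiated. Host mice carried a floxed Sfrp2 gene or lacked Sfrp2 in cells with Col1a2 promoter activity, that is in fibroblasts. Sfrp2 encodes a secreted Wnt-binding protein. The Flox+ICI library came from a floxed host given an immune checkpoint inhibitor alone. Radiation was added in the Flox+RI library, and the library labelled CKO+RI was made after the same pair of treatments. The labels give the tissue only as tumour and do not say which lesion was taken. Alveolar type 2 cell-like cells, which line the air spaces of the lung, made up 4.35% (3.95 to 4.77) of the kept cells of Flox+ICI, 0.615% (0.482 to 0.774) of those of Flox+RI and 1.94% (1.66 to 2.26) of those of the library labelled CKO+RI.

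Depth differed between the libraries. The matrices held 10842 barcodes and 75543561 UMIs (transcript molecules) for Flox+ICI, 13340 and 101840883 for Flox+RI, and 9300 and 161250286 for the library labelled CKO+RI. After filtering, 9777, 11706 and 8383 cells remained, in that order, with median UMIs of 3018, 2576.5 and 13406 per cell. The median was thus 5.203 times as high in the library labelled CKO+RI as in Flox+RI. With 1 library per group no difference has a replicate check, and no test between groups was possible. Intervals in parentheses after shares, levels and their ratios are exact 95% intervals and cover counting error only. Those after medians, and after the ratio of median gene lengths, are 95% intervals over list members or genes.

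Sfrp2 (ENSMUSG00000027996; GRCm38 chromosome 3, 83766321 to 83774316, plus strand, 3 exons) was the targeted gene. It was not lower in the library labelled CKO+RI. Over all kept cells, 6 Sfrp2 UMIs were counted in Flox+ICI, 3 in Flox+RI and 46 in the library labelled CKO+RI. Its level in UMIs per 1000000 class UMIs (CPM) in the library labelled CKO+RI was 9.25 times that in Flox+RI (2.97 to 46.5), and 2.41 times when no doublets were removed. Fibroblast-like cells held 5 Sfrp2 UMIs in 131 cells of the library labelled CKO+RI, 1 in 43 cells of Flox+RI and 2 in 237 cells of Flox+ICI. The ratio of the level in fibroblast-like cells, 2.79 (0.312 to 132), left the direction open. A UMI was found in 1.53% of these cells in the library labelled CKO+RI (0.185 to 5.41) and in 2.33% in Flox+RI (0.0589 to 12.3), at median depths of 3186 and 6900 UMIs. Thinned to 2000 UMIs per cell, which left out 44 and 8 cells, the shares were 2.30% (0.280 to 8.06) of 87 cells and 0% (0 to 10.003) of 35 cells. Neutrophil-like cells, which should lack the transcript, had no Sfrp2 UMI in any library, at a median of 1812.5 UMIs in the library labelled CKO+RI and 723 in Flox+RI.

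Most Sfrp2 UMIs of the library labelled CKO+RI came from mesothelial cell-like cells, the lining of the pleura, where 30 UMIs fell in 10 of 26 cells. That was 139.7 CPM (94.2 to 199). It was 7.76 times the level in Flox+RI at a floor of 3 counts, since 0 UMIs were found there in 13 cells. The lower bound of the exact interval of the ratio was 5.93. Which part of Sfrp2 was deleted is not known here, and a 3' tag that lies outside the deleted part checks nothing. The genotype of the library labelled CKO+RI therefore rests on its title. Every direction given for it below goes by that label, which the Sfrp2 counts do not back. They were higher over all kept cells, and in fibroblast-like cells, where the deletion was meant to act, they left the direction open.

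**Figure D1:**
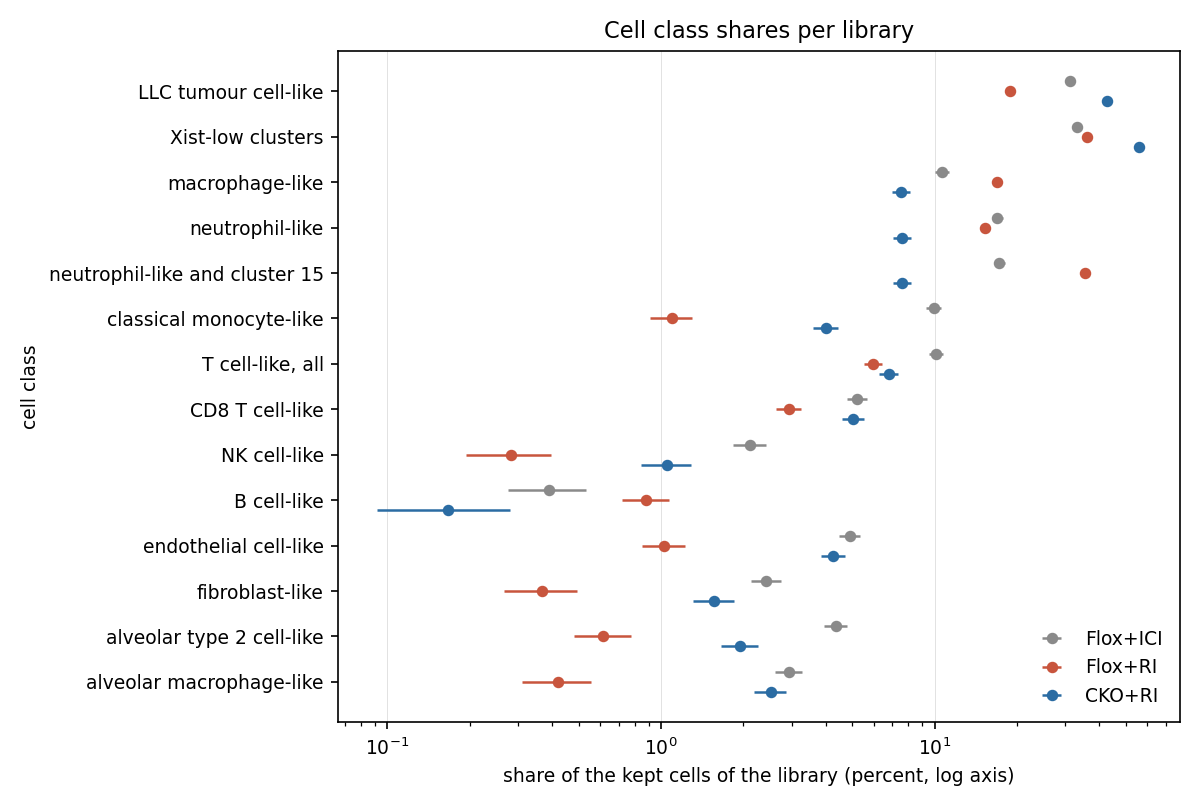
Share of the kept cells of each library (x axis, percent, log scale) held by each cell class (y axis). Points are the 3 libraries, 1 per group, and lines are exact 95% binomial intervals, which cover counting error only. Macrophage-like cells held 16.9% of Flox+RI and 7.56% of the library labelled CKO+RI, while endothelial cell-like cells held 1.03% and 4.26%.

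Sfrp2 deletion under the combined treatment was addressed by the library labelled CKO+RI against Flox+RI. By that label, endothelial cell-like, fibroblast-like and classical monocyte-like cells held larger shares than in Flox+RI, and macrophage-like cells a smaller one. CD8 T cell-like cells, the cytotoxic lineage, were 5.05% (4.59 to 5.54) of the kept cells against 2.94% (2.64 to 3.26), a ratio of 1.72 (1.49 to 1.99), which turned to 0.744 without cluster T11, an alternative chosen after the data were seen. Macrophage-like cells were 7.56% (7.01 to 8.15) against 16.9% (16.3 to 17.6), 2.24-fold lower. Genes induced by interferon gamma were higher in tumour, macrophage-like and endothelial cell-like cells of the library labelled CKO+RI. Cytotoxic genes such as Prf1 (perforin) and Gzmb (granzyme B) were higher in the CD8 T cell-like cells of that library, at 7.003-fold and 4.10-fold. The same Flox+RI library also stands in the comparison with Flox+ICI below. A trait of Flox+RI therefore appears in both comparisons, with opposite sign, and cannot be told apart from deletion or radiation. For Cxcl9 in macrophage-like cells, Flox+ICI (464 CPM) lay near the library labelled CKO+RI (433) and not Flox+RI (31.7). For Ccl4 in CD8 T cell-like cells, Flox+ICI (119) lay near Flox+RI (96.8) and not the library labelled CKO+RI (811).

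Endothelial cell-like cells made up 4.26% (3.84 to 4.71) of the kept cells of the library labelled CKO+RI and 1.03% (0.851 to 1.22) of those of Flox+RI, a ratio of 4.15 (3.37 to 5.15). Fibroblast-like cells, at 1.56% and 0.367%, had a ratio of 4.25 (2.99 to 6.15). Within them, cluster S4, led by Mgp, Col1a1 and Col1a2, held 0.322% of the kept cells of the library labelled CKO+RI, 0.333% of Flox+RI and 0.297% of Flox+ICI, and the other fibroblast-like clusters carried the difference. Alveolar type 2 cell-like and alveolar macrophage-like cells, which belong to lung outside a tumour, also held larger shares, with ratios of 3.16 (2.38 to 4.23) and 6.01 (4.39 to 8.38). Classical monocyte-like cells were 4.01% against 1.09%, and NK cell-like cells 1.05% against 0.282%. All T cell-like cells together were 6.80% against 5.96%, a ratio of 1.14 (1.02 to 1.28) that turned to 0.662 without cluster T11. Regulatory T cell-like cells, which restrain other T cells, were 0.322% against 0.777%, and B cell-like cells 0.167% against 0.880%. Neutrophil-like cells, at class medians of 1812.5 and 723 UMIs per cell, were 7.59% against 15.3%, a ratio of 0.495 (0.452 to 0.542). It was 0.214 (0.197 to 0.233) with cluster 15 counted in and 1.31 (1.17 to 1.47) for cluster 0 alone, both chosen after the data were seen. The unnamed cluster 15, with few UMIs per cell and led by Ccl3 and Il1rn, held 20.1% of Flox+RI but 0.0119% of the library labelled CKO+RI. Since 98.7% of its cells came from Flox+RI, it stands for that library as much as for a type. All unnamed clusters together held 38.5% of Flox+RI, 16.7% of the library labelled CKO+RI and 4.48% of Flox+ICI. Unlike parts of the libraries thus lie outside the named classes.

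LLC tumour cell-like cells were 42.8% (41.7 to 43.9) of the kept cells of the library labelled CKO+RI and 18.9% (18.2 to 19.6) of those of Flox+RI, a ratio of 2.26 (2.15 to 2.39). Clusters 2 and 8 were Xist-low but carried no name, under a threshold of 20 Xist CPM that was set after the clusters were seen. The leading genes of cluster 2, among them Lum, Dcn, Ccl11 and Col3a1, held more markers of fibroblasts. Those of cluster 8, among them R3hdml, Il1rl1 and Slc2a5, held more markers of gamma-delta T cells or innate lymphoid cells. This count kept cluster 8 unnamed but does not make it lymphoid. Its Xist level was 2.38 CPM and its median depth 6.47 times that of its own library. The T cell-like cluster 17 had 343.95 CPM and 0.441 times. Cluster 2 held 0.0614%, 0.120% and 12.1% of Flox+ICI, Flox+RI and the library labelled CKO+RI, and cluster 8 held 1.85%, 17.1% and 1.12%. With clusters 2 and 8 added to the tumour class, a pool that leaves out the erythroid cell-like and platelet or megakaryocyte-like clusters under the same threshold, the shares of the library labelled CKO+RI and Flox+RI were 56.0% and 36.2%, a ratio of 1.55 (1.49 to 1.62).

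In CD8 T cell-like cells, effector and checkpoint genes were higher in the library labelled CKO+RI and genes of naive and stem-like T cells lower. Of the cytotoxic effector list, 9 of 13 measured members were higher, 2 lower and 2 had an interval holding 1, with a median log2 ratio of 0.95 (0.02 to 2.77 over members). Its percentile among 10000 random lists of matched size and expression was 100, which, like the percentiles of other lists, describes these libraries only. Prf1 was 7.003 times (4.43 to 11.8) and Gzmb 4.10 times (3.23 to 5.28) its Flox+RI level. Among checkpoint receptors and other exhaustion genes, 8 of 12 measured members were higher, 1 lower and 3 had an interval holding 1 (median 1.17). Havcr2 (TIM-3), Lag3 and Pdcd1 (PD-1) were 5.58-fold, 4.996-fold and 2.83-fold higher. The naive and stem-like list had 0 of 8 members higher and 5 lower (median -0.88), among them Bach2, Tcf7 and Il7r, which were 3.98-fold, 3.28-fold and 2.78-fold lower. By the rule of size, the genes highest in the library labelled CKO+RI were Hspa1a, a heat shock protein, at 325 against 30.9 CPM, and the chemokines Ccl4 (811 against 96.8) and Ccl3 (605 against 86.5). Hspa1a and Ccl4 were also higher than in both Flox libraries in most of the host classes measured, and the dissociation stress list that holds Hspa1a had 6 members higher and 5 lower in these cells. The genes lowest were Astl, an oocyte metalloprotease (9.24 against 222), Pde2a, a cyclic nucleotide phosphodiesterase (9.90 against 103), and the transcription factor Nfe2l3 (14.5 against 124). Astl, Pde2a and Nfe2l3 were lower than in Flox+RI in 5 of 5, 3 of 4 and 6 of 6 host classes measured. The ratios of Ccl3 and Pde2a at Leiden resolution 2.0, and of Nfe2l3 with at most 10% mitochondrial UMIs, kept their direction but were far smaller differences. Different clusters held the class. Cluster T11, whose median depth was 0.219 times that of its own library, had 244 cells in the library labelled CKO+RI, 8 in Flox+RI and 16 in Flox+ICI. That was 57.7% of the class in the library labelled CKO+RI and 2.33% in Flox+RI, and clusters T7, T3 and T4 held 9.46%, 4.96% and 22.5% against 60.5%, 31.4% and 2.33%. Without T11 the medians of the 3 lists were 1.22, 1.37 and -1.45.

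Macrophage-like cells of the library labelled CKO+RI had more antigen presentation transcript and a lower median of the immunosuppressive list. All 7 measured MHC class II genes were higher (median log2 ratio 1.01, 95% interval over members 0.62 to 1.53, percentile 99.98 among random lists), with H2-Eb1 at 2.90-fold and H2-Aa at 2.48-fold. Of the MHC class I and interferon gamma list, 11 of 14 measured members were higher, 1 lower and 2 had an interval holding 1 (median 0.50). Cxcl9, a ligand that draws CXCR3-bearing T cells, stood at 433 against 31.7 CPM, 13.6-fold higher (12.02 to 15.5), and the GTPases Iigp1 and Gbp2 were 8.07-fold and 6.30-fold higher. Of the immunosuppressive macrophage list, 4 of 13 measured members were higher, 7 lower and 2 had an interval holding 1 (median -0.53). Its members moved apart. Hmox1, which degrades haem, was 3.28-fold lower, while Ccl8, Folr2 and the mannose receptor Mrc1 were 7.96-fold, 3.92-fold and 2.36-fold higher. The inflammatory list was split as well, with 8 members higher and 4 lower. Il12b, Ccl4 and Nos2 were 5.55-fold, 4.33-fold and 3.64-fold higher, and Il6 6.84-fold lower. Hypoxia genes were mostly lower (7 of 12, median -0.23). The rule of size named Cxcl9, the chemokine Ccl8 (2416 against 303), which was also higher across most host classes, and the lectin Mgl2 (129 against 15.4) as highest. It named Astl (1.003 against 102), the glutathione transferase Gsto2 (2.41 against 105) and Ankdd1a (1.003 against 44.9) as lowest. Gsto2 was lower in 2 of 2 and Ankdd1a in 3 of 3 host classes measured. Cluster 10, with Ccl8, H2-Eb1, Mrc1 and H2-Aa among its leading genes, held 86.3% of the class in the library labelled CKO+RI against 41.3% in Flox+RI. There cluster 9, led by Ctss, Hmox1 and Gpnmb, held 58.7%. Values were not taken within these clusters, so a different mix of them cannot be separated from a change within cells.

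In endothelial cell-like cells, antigen presentation genes were higher in the library labelled CKO+RI and genes of sprouting vessels lower. All 14 measured members of the MHC class I and interferon gamma list were higher (median log2 ratio 0.96, 95% interval over members 0.77 to 1.52, percentile 100 among random lists), Gbp2 by 4.17-fold. Cxcl9 had 83 UMIs against 1, a ratio of 54.2 (9.47 to 2168). All 7 MHC class II genes were higher (median 2.57), at median depths of 1454 and 4215 UMIs per cell. Macrophage markers in these cells had a median log2 ratio of 0.34 (-0.89 to 1.08), a check made after the data were seen. These markers moved apart, with Spp1 at 460 against 164 CPM and Trem2 at 4.65 against 21.4. Their median therefore cannot decide whether MHC class II RNA was carried over from other cells. H2-Aa and the invariant chain Cd74 were 9.03-fold and 6.25-fold higher. Ciita, the transactivator of these genes, had 27 UMIs against 0, which was 5.88-fold higher when Flox+RI was set at the floor of 3 counts. Of the tip cell and VEGF list, 2 of 14 measured members were higher, 8 lower and 4 had an interval holding 1 (median -0.51). Apln (apelin) and Angpt2 (angiopoietin-2) were 5.78-fold and 4.97-fold lower, and Vegfa was 3.33-fold higher. The adhesion and recruitment list had 5 members higher and 1 lower (median 1.2002), Ccl2 being 6.96-fold higher, but its median turned to -0.31 when each cell had the same weight. Named by size, Hpgd, which inactivates prostaglandins, was at 1016 against 59.8 CPM, 17.0-fold higher (12.5 to 23.7). It was higher in 3 of 3 host classes measured (median log2 ratio 2.22). Stox2 was at 102 against 5.70, and Sema5a, a semaphorin, had a ratio of 47.7 (8.30 to 1909.7) on 73 UMIs against 1. Without doublet removal the ratio of Sema5a fell just below that interval. Ccn2, a matricellular growth factor (24.2 against 266), Angptl4 (14.0 against 147) and the tip cell marker Esm1 (24.2 against 212) were lowest. Cluster 13 held 84.3% and 95.8% of the class, and cluster 18, with Car4 and Ednrb among its leading genes, 15.7% and 4.17%. Alveolar type 2 cell-like cells differed in share the same way (1.94% against 0.615%). Vessels of lung and of tumour were not told apart within the class, so a different mix of them cannot be separated from a change within cells.

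Neutrophil-like cells took the place of fibroblast-like cells among the classes with named genes, since Flox+RI had only 43 of the latter against a minimum of 50. The genes highest in the library labelled CKO+RI by size were Ngp, Ly6g and Mgst1. Ngp was at 1534 against 117 CPM, 13.2-fold higher (11.2 to 15.6), the surface protein gene Ly6g at 549.7 against 81.3 and the glutathione transferase Mgst1 at 310.0 against 48.2. With at least 500 genes per barcode the ratio of Ngp was still higher in the library labelled CKO+RI but fell far below that interval. Camp (cathelicidin) and Ltf (lactoferrin) were 16.6-fold and 3.92-fold higher within the maturity list, of which 7 of 13 measured members were higher, 4 lower and 2 had an interval holding 1. Of the type I interferon response list, 9 of 12 measured members were higher, 1 lower and 2 had an interval holding 1 (median log2 ratio 1.22), with Ifit3, Oasl1 and Zbp1 at 4.18-fold, 3.79-fold and 3.11-fold. Lowest by size were Il23a, a subunit of interleukin-23 (7.62 against 416), the coagulation factor gene F10 (25.4 against 325) and the fractalkine receptor Cx3cr1 (13.6 against 179). F10 and Cx3cr1 were lower in all 4 and all 5 host classes in which they were measured. Hypoxia genes had 6 of 11 members lower (median -0.49). Cluster 0, with Ngp among its leading genes, held 96.2% of the class in the library labelled CKO+RI and 36.3% in Flox+RI. There cluster 14, led by Il1r2, Il1b and Tnf, held 63.7%. A different mix of these clusters cannot be separated from a change within cells.

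In LLC tumour cell-like cells of the library labelled CKO+RI, interferon gamma targets and cell cycle genes were higher and hypoxia and TGF-beta response genes lower. Of the MHC class I and interferon gamma list, 12 of 14 measured members were higher, 1 lower and 1 had an interval holding 1 (median log2 ratio 0.72, 95% interval over members 0.38 to 3.50, percentile 100 among random lists). Iigp1, Gbp2 and Cxcl9 were 24.9-fold, 12.2-fold and 11.99-fold higher. Of the cell cycle list, 11 of 14 measured members were higher, 3 lower and 0 had an interval holding 1 (median 0.41), with Ccnb2 at 1.72-fold and Cenpa at 1.71-fold. Hypoxia genes had 2 members higher and 9 lower (median -0.31), Vegfa being 3.35-fold lower. TGF-beta response genes had 2 higher and 9 lower (median -0.85), with Cthrc1 6.97-fold lower and Col8a1 4.97-fold higher. Sox11, a developmental transcription factor, had 1834 UMIs against 0, 204 times the level at the floor of 3 counts, with an exact lower bound of 165. Its level in Flox+ICI was 20.9 CPM, close to the 19.3 of the library labelled CKO+RI. Tmem121 had a ratio of 81.3 (22.4 to 673) on 488 UMIs against 2, and Scin, which severs actin filaments, was 43.9-fold higher. Lower were R3hdml (0.348 against 14.9 CPM), Faim2, an inhibitor of Fas-induced death (0.506 against 13.5), and Elfn2 (0.390 against 10.1). Faim2 and Elfn2 lie on chromosome 15, whose genes as a whole were higher in the tumour cells of Flox+RI. Tmem121 lies in a part of chromosome 12, from 110 to 120 Mb, whose median was lower there. Clusters 1 and 4 held 39.3% and 36.3% of the class in the library labelled CKO+RI, and cluster 7, led by Ereg and Sema3a, held 56.3% in Flox+RI.

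Shares of these classes depended on how barcodes were kept and on how clusters were split and named. Without doublet removal the ratio for CD8 T cell-like cells was 34.6. That for all T cell-like cells stayed within its interval of 1.02 to 1.28 there, so the change lay in how T cells were split and named. With at least 500 genes per barcode the ratio for neutrophil-like cells turned to 2.09. That for regulatory T cell-like cells turned to 1.46 when genes that differed between libraries were kept out of the clustering, and TMM scaling would have added 0.20 to the log2 ratios of tumour cells and 0.22 to those of neutrophil-like cells.

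**Figure D2:**
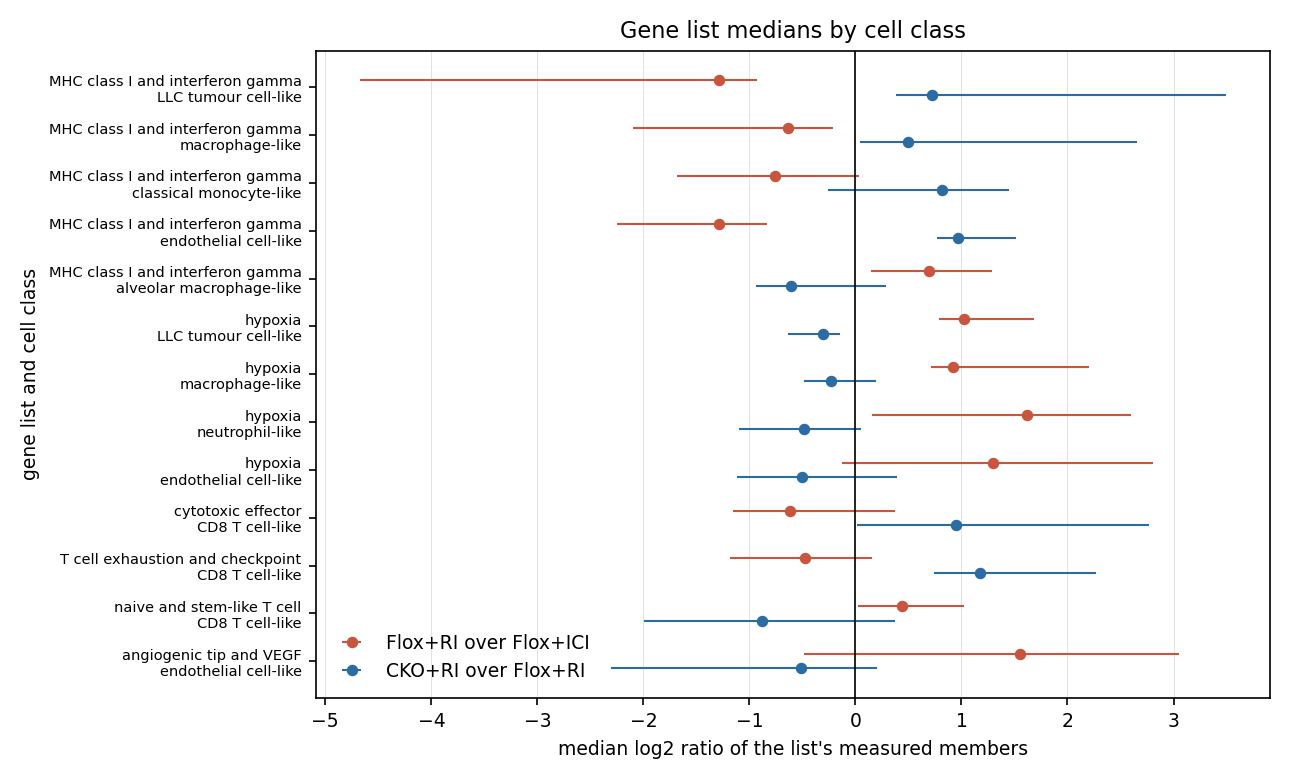
Median log2 ratio (x axis) of the measured members of gene lists in the cell classes named on the y axis, for Flox+RI over Flox+ICI and for the library labelled CKO+RI over Flox+RI, with 1 library per group. Lines are 95% intervals of the median over the list members, and 0 is no difference. Both comparisons use the same Flox+RI library. The MHC class I and interferon gamma median in tumour cells was -1.29 in the first comparison and 0.72 in the second.

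The addition of radiation, given at the subcutaneous tumour, was addressed by Flox+RI against Flox+ICI, which share the host genotype. This Flox+RI library was also set against the library labelled CKO+RI above, so the comparisons are not independent. Interferon gamma targets were lower in Flox+RI in tumour, macrophage-like and endothelial cell-like cells, and hypoxia genes higher in tumour cells, macrophage-like and neutrophil-like cells. In tumour cells Iigp1, a GTPase of cell-autonomous immunity, was 91.4-fold lower and Adm (adrenomedullin), a hypoxia target, 4.92-fold higher. Macrophage-like cells held 16.9% (16.3 to 17.6) of Flox+RI and 10.7% (10.1 to 11.3) of Flox+ICI, a ratio of 1.59 (1.47 to 1.71). CD8 T cell-like cells held 2.94% (2.64 to 3.26) and 5.21% (4.77 to 5.67), a ratio of 0.564 (0.491 to 0.648).

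Classical monocyte-like cells were 1.09% (0.913 to 1.30) of Flox+RI against 9.92% (9.34 to 10.5) of Flox+ICI, 9.07-fold lower. NK cell-like cells were 7.47-fold lower (0.282% against 2.11%), endothelial cell-like cells 4.77-fold (1.03% against 4.89%) and fibroblast-like cells 6.60-fold (0.367% against 2.42%). Alveolar type 2 cell-like and alveolar macrophage-like cells moved the same way, with ratios of 0.141 (0.109 to 0.182) and 0.143 (0.103 to 0.194), so these lung cells were scarce in the Flox+RI library. All T cell-like cells were 5.96% against 10.1%, a ratio of 0.589 (0.534 to 0.649). Regulatory T cell-like cells were 1.65 (1.15 to 2.41) times and B cell-like cells 2.26 (1.55 to 3.38) times as frequent in Flox+RI. Neutrophil-like cells had a ratio of 0.904 (0.845 to 0.967), which turned to 2.05 (1.94 to 2.17) with cluster 15 counted in and was 0.349 (0.318 to 0.383) for cluster 0 alone. The ratio for LLC tumour cell-like cells was 0.607 (0.574 to 0.641) and turned to 1.09 (1.04 to 1.15) with clusters 2 and 8 pooled in, since cluster 8, led by R3hdml and Il1rl1, held 17.1% of Flox+RI.

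LLC tumour cell-like cells of Flox+RI had all 14 measured members of the MHC class I and interferon gamma list lower (median log2 ratio -1.29, 95% interval over members -4.68 to -0.93, percentile 0 among random lists). Iigp1 stood at 0.696 against 63.6 CPM and Gbp2 at 2.72 against 84.2. Cxcl9 was 27.1-fold lower. All 12 hypoxia genes were higher (median 1.02), among them Bnip3 (4.80-fold), the carbonic anhydrase Car9 (3.23-fold) and Vegfa (2.98-fold). Cell cycle genes were mostly lower, 12 of 14, by small amounts (median -0.23), such as 1.41-fold for Ccnb2 and 1.40-fold for Stmn1. The TGF-beta response list had 7 members higher and 4 lower, with Cthrc1 4.40-fold higher. By size, Elfn2 (10.1 against 0.351), the alarmin Il33 (51.9 against 3.10) and Bmp5, a bone morphogenetic protein (9.69 against 0.527), were highest in Flox+RI. Sox11, at 0 UMIs in Flox+RI and 20.9 CPM in Flox+ICI, was 219.9-fold lower when Flox+RI was set at the floor of 3 counts. Cluster 3, led by Gbp2 and Iigp1, held 27.1% of the class in Flox+ICI and 1.26% in Flox+RI. Without it the list median was -1.05, an alternative added after the data were seen.

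Chromosome 15 genes were higher as a group in the tumour cells of Flox+RI than in those of either other library. The median log2 ratio of chromosome 15 genes, relative to all measured genes, was 0.43 (0.39 to 0.47, 523 genes) over the library labelled CKO+RI and 0.36 (0.33 to 0.41, 501 genes) over Flox+ICI. The medians of the other whole chromosomes lay between -0.23 and 0.11 and between -0.15 and 0.14. In macrophage-like cells, which come from the host, the chromosome 15 median over the library labelled CKO+RI was 0.12 (0.05 to 0.16). Elfn2 (GRCm38 chromosome 15, 78667331 to 78718771) and Faim2 (chromosome 15, 99497012 to 99528165) lie on this chromosome, while Sox11, Tmem121 and Scin lie on chromosome 12. One part of chromosome 12, from 110 to 120 Mb, was lower in tumour cells of Flox+RI. Its median was -0.63 (60 genes) over the library labelled CKO+RI and -0.51 (58 genes) over Flox+ICI. Tmem121 (113185930 to 113189523) lies in this part, and Sox11 and Scin do not. The cause of this regional difference was not tested.

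**Figure D3:**
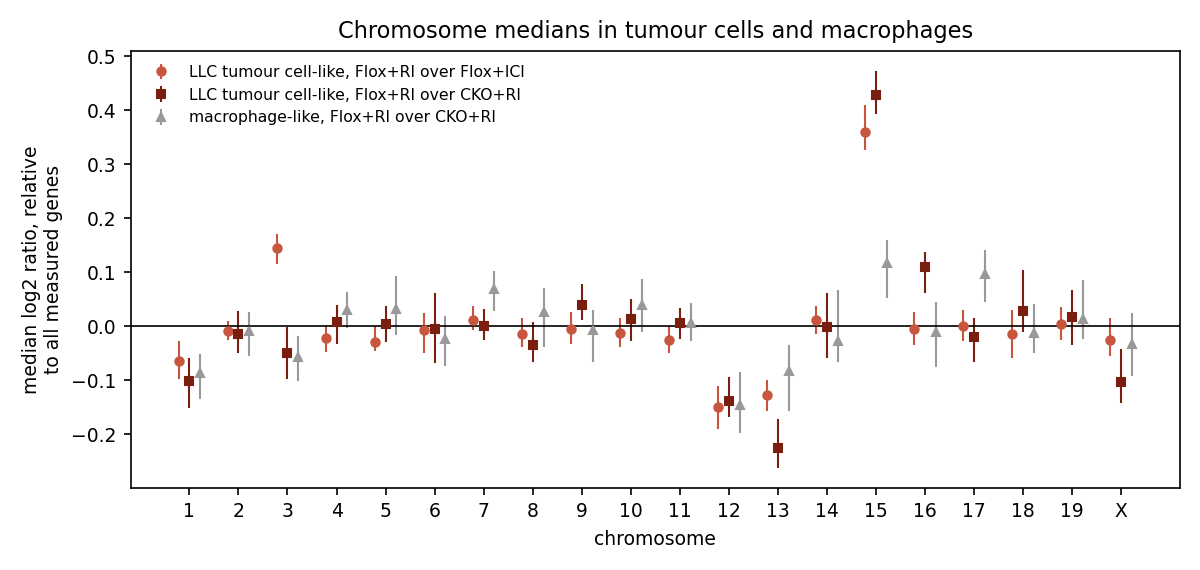
Median log2 ratio of the measured genes of each chromosome (y axis, relative to all measured genes) by chromosome (x axis). Red marks are LLC tumour cell-like cells of Flox+RI over each other library, grey triangles are macrophage-like cells, and lines are 95% intervals over genes. The tumour medians of chromosome 15, 0.43 and 0.36, lay above those of all other chromosomes plotted.

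Macrophage-like cells of Flox+RI had less antigen presentation transcript and more hypoxia transcript. All 7 MHC class II genes were lower (median log2 ratio -1.06, 95% interval over members -1.36 to -0.55, percentile 0 among random lists), with H2-Eb1 and H2-Aa 2.56-fold and 2.39-fold lower. Of the MHC class I and interferon gamma list, 0 of 14 measured members were higher, 12 lower and 2 had an interval holding 1 (median -0.64). Cxcl9 was 14.6-fold lower, at 31.7 against 464 CPM, and Gbp2 and the serpin Serpina3g were 6.77-fold and 5.66-fold lower. Hypoxia genes were higher for 11 of 12 members (median 0.92), among them Egln3, a HIF prolyl hydroxylase, at 12.3-fold (8.25 to 19.3), Adm at 7.33-fold and Bnip3 at 3.52-fold. The immunosuppressive list was split, 6 members higher and 6 lower. Arg1 (arginase) and the scavenger receptor Cd163 were 5.03-fold and 2.79-fold higher, and Gpnmb was 2.56-fold lower. Of the inflammatory list, 8 of 12 measured members were higher, 3 lower and 1 had an interval holding 1, Il6 being 3.55-fold higher. In alveolar macrophage-like cells, of which Flox+RI had only 49, the MHC class I and interferon gamma list went the other way (median 0.70, 4 of 11 members higher and 0 lower). Saa3, an acute phase protein, was at 1961 against 72.2 CPM, 27.2-fold higher (24.6 to 30.1), and Ly6i at 187 against 26.3. Saa3 was higher in CD8 T cell-like cells too, at 63.8 against 1.91. Clusters 9 and 10 held 58.7% and 41.3% of the class in Flox+RI and 52.4% and 47.6% in Flox+ICI.

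CD8 T cell-like cells of Flox+RI carried less effector transcript. Of the cytotoxic effector list, 1 of 13 measured members was higher, 7 lower and 5 had an interval holding 1 (median log2 ratio -0.62, 95% interval over members -1.16 to 0.37, percentile 0 among random lists). Klrg1, a receptor of differentiated effector cells, and Prf1, Gzma and Gzmb were 4.30-fold, 2.85-fold, 2.24-fold and 2.13-fold lower. Of the exhaustion and checkpoint list, 0 of 11 measured members were higher, 4 lower and 7 had an interval holding 1 (median -0.47), with Lag3, Havcr2 and Pdcd1 3.55-fold, 2.36-fold and 2.21-fold lower. Over all kept cells, Ifng, the interferon gamma gene itself, had 2.64 CPM (2.31 to 3.01) in Flox+RI and 8.15 (7.48 to 8.87) in Flox+ICI. Naive and stem-like genes had 5 of 10 members higher and 0 lower, Il7r and Tcf7 at 2.24-fold and 2.03-fold. By size, the immediate early genes Fos (249 against 88.7 CPM) and Fosb (163 against 58.1) and the growth factor homologue Fgf13 (237 against 83.9) were highest. The ratio of Fosb, 2.80 (1.98 to 3.97), turned to 0.393 with at most 10% mitochondrial UMIs per barcode. Lowest were Irf8, an interferon regulatory factor (8.24 against 91.5), Nrgn, with 3 UMIs against 223 and a ratio of 0.0291 (0.00595 to 0.0860), and Scgb1a1 (98.8 against 711). Without doublet removal the ratios of Irf8 and Nrgn were 0.560 and 0.207. Scgb1a1 encodes the secretory product of club cells and was found in every class listed, at 483 CPM in macrophage-like and 259 in tumour cells of Flox+ICI. Cluster T7 held 60.5% of the class in Flox+RI and 47.0% in Flox+ICI, and cluster T4 2.33% and 21.2%.

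Endothelial cell-like cells of Flox+RI had tip cell genes higher and antigen presentation genes lower. Of the tip cell and VEGF list, 10 of 14 measured members were higher, 3 lower and 1 had an interval holding 1 (median log2 ratio 1.55, 95% interval over members -0.48 to 3.05, percentile 100 among random lists), with Angpt2, Esm1 and Apln at 9.99-fold, 8.39-fold and 8.33-fold. All 14 members of the MHC class I and interferon gamma list were lower (median -1.28). Iigp1 and the transcription factor Irf1 were 5.39-fold and 4.77-fold lower, and Cxcl9 had a ratio of 0.0148 (0.000373 to 0.0845). All 7 MHC class II genes were lower (median -3.50), H2-Aa and Cd74 by 14.3-fold and 12.4-fold. Median depths were 4215 and 1363.5 UMIs per cell. By the same check the macrophage markers had a median log2 ratio of -0.29 (-0.84 to 0.72) in these cells. The markers moved apart here too, so RNA carried over from other cells was not decided. Ciita, at 0 UMIs against 33, was 6.74-fold lower when Flox+RI was set at the floor of 3 counts. The adhesion and recruitment list had 1 member higher and 6 lower (median -1.02), Cxcl10 and the adhesion molecule Icam1 being 8.80-fold and 2.71-fold lower. Named by size, Tnfrsf9 (4-1BB) was at 423 against 28.8 CPM, 14.7-fold higher (10.2 to 21.8), the angiogenic factor Pgf at 222 against 18.3 and the secretoglobin Scgb3a1 at 349 against 21.8. Hpgd (59.8 against 2029), Sema5a (1 UMI against 174, ratio 0.00939 (0.000236 to 0.0530)) and Scgb1a1 (21.4 against 2560), again in all classes, were lowest. Cluster 13 held 95.8% of the class in Flox+RI and 81.4% in Flox+ICI, and cluster 18 held 4.17% and 18.6%. Alveolar type 2 cell-like cells were 0.615% of Flox+RI and 4.35% of Flox+ICI. Here too, a different mix of lung and tumour vessels cannot be separated from a change within cells.

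In neutrophil-like cells of Flox+RI, most hypoxia genes were higher and most members of the maturity and tumour neutrophil list lower. Hypoxia genes had 9 of 11 members higher and 0 lower (median log2 ratio 1.62, 95% interval over members 0.15 to 2.60, percentile 100 among random lists), with Ankrd37 and Egln3 at 11.4-fold and 6.11-fold. Of the latter list, 4 of 13 measured members were higher, 8 lower and 1 had an interval holding 1. Camp and Ltf were 53.2-fold and 13.1-fold lower, while Siglecf, which marks tumour neutrophils, and Ccl3 were 5.53-fold and 4.73-fold higher. The type I interferon list had 3 members higher, 1 lower and 7 undecided (median 0.09). By size, H2-Q6, a non-classical MHC class I gene, was at 183 against 8.85 CPM, 20.7-fold higher (12.7 to 36.1), and Klhl6 at 314 against 58.8. Lowest were Ngp (117 against 3215), Ifitm6 (330.2 against 3141) and Ly6g (81.3 against 784). Cluster 14 held 63.7% of the class in Flox+RI and 6.09% in Flox+ICI, at class medians of 723 and 1049 UMIs per cell. Ngp and Ifitm6 were among the leading genes of the other cluster, cluster 0. Here too, a different mix of clusters cannot be separated from a change within cells.

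The direction of the tumour share in this comparison also turned at Leiden resolution 0.5, to a ratio of 1.11, and that of regulatory T cell-like cells turned to 0.592 when genes that differed between libraries were kept out of the clustering. The ratio for CD8 T cell-like cells was 0.0874 without doublet removal and 0.150 with at most 10% mitochondrial UMIs, and TMM scaling would have added 0.11, 0.12 and -0.42 to the log2 ratios of tumour, macrophage-like and neutrophil-like cells.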

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

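The tumour class pooled with clusters 2 and 8, the denominator outside this pool, cluster 15 counted in, cluster 0 alone, tumour cells without cluster 3 and T cell-like cells without cluster T11 were chosen after seeing the data, and the other alternatives before. Of the planned ratios of shares, 135 of 198 stayed within their interval, 55 left it in the same direction or from a value not called, and 8 turned. For named genes these were 358, 117 and 1 of 476, with 7.14-fold as the largest move, of Nrgn, for list medians 251, 4 and 1 of 256, and for Sfrp2 29, 2 and 0 of 31. Among those added later, 5 of 34 shares turned, and 0 of 24 genes and 0 of 24 lists. Ratios below are of shares, CKO+RI over Flox+RI first and Flox+RI over Flox+ICI second where 2 are given. The tumour share of Flox+RI over Flox+ICI turned at Leiden resolution 0.5 (1.11), without genes that differed between libraries among the variable genes (1.04) and with clusters 2 and 8 pooled in (1.09), where CKO+RI over Flox+RI was 1.43, 1.64 and 1.55. The neutrophil-like share of Flox+RI over Flox+ICI turned at resolutions 0.5 (2.05) and 2.0 (1.25), of leukocyte classes (1.18) and with cluster 15 counted in (2.05), and that of CKO+RI over Flox+RI with at least 500 genes (2.09) and for cluster 0 alone (1.31). The CD8 T cell-like share of CKO+RI over Flox+RI turned without cluster T11 (0.744), as did that of all T cell-like cells (0.662), where Flox+RI over Flox+ICI had 0.569 and 0.592. Regulatory T cell-like shares turned without differing variable genes (1.46 and 0.592), where CD8 T cell-like cells had 2.12 for CKO+RI over Flox+RI. Fosb in CD8 T cell-like cells of Flox+RI over Flox+ICI turned to 0.393 with at most 10% mitochondrial UMIs, and the median log2 ratio of adhesion and recruitment in endothelial cell-like cells of CKO+RI over Flox+RI to -0.31 with the mean over cells. Other ratios of genes left their interval with a move over 3-fold. In CD8 T cell-like cells of Flox+RI over Flox+ICI, Nrgn was at 0.207 and Irf8 at 0.560 without doublet removal, and Nrgn at 0.106 with at most 10% mitochondrial UMIs. In those of CKO+RI over Flox+RI, Nfe2l3 was at 0.433 with that limit, and Ccl3 and Pde2a at 1.96 and 0.342 at resolution 2.0. For CKO+RI over Flox+RI, Sema5a in endothelial cells was at 8.17 without doublet removal and Ngp in neutrophil-like cells at 4.30 with at least 500 genes. With at most 10% mitochondrial UMIs, CD8 T cell-like cells had 16.6 and 0.150 and tumour cells 3.02 and 0.447. Without doublet removal, CD8 T cell-like cells had 34.6 and 0.0874, tumour cells 1.47 and 0.702, macrophage-like cells 0.607 for CKO+RI over Flox+RI, and the Sfrp2 level over all kept cells 2.41. With at least 500 genes, the ratios were 3.03 and 0.468 for CD8 T cell-like, 1.48 and 0.797 for tumour, 1.02 and 0.667 for all T cell-like, 3.14 and 0.260 for endothelial and 0.359 and 1.82 for macrophage-like cells. At resolution 2.0 they were 2.31 for CD8 T cell-like and 0.587 for macrophage-like cells of CKO+RI over Flox+RI, and 0.511 for tumour cells of Flox+RI over Flox+ICI. Outside the tumour class they were 2.43 and 0.479 for CD8 T cell-like, 1.62 and 0.49997 for all T cell-like, 0.633 and 1.35 for macrophage-like and 5.89 for endothelial cells of CKO+RI over Flox+RI. Outside the pooled tumour clusters, CKO+RI over Flox+RI had 2.49, 1.66, 0.648 and 6.03 in the same order. Of leukocyte classes, the ratios were 2.37 and 0.736 for CD8 T cell-like, 1.57 and 0.768 for all T cell-like and 0.615 and 2.07 for macrophage-like cells. The leukocyte classes leave out the unnamed cluster 15, which held 20.1% of Flox+RI, 0.307% of Flox+ICI and 0.0119% of CKO+RI. Counted in, it would lower the leukocyte shares of Flox+RI far more than those of the other libraries. Ratios with it in this denominator were not computed. The cause of the moves under these alternatives was not tested. The mean over cells has no value for Sox11, at 0 in 1 library, nor resolution 2.0 for Irf8 and Nrgn in CD8 T cell-like cells of Flox+RI over Flox+ICI, with too few UMIs. Depth limits genes of low level in shallow classes, such as neutrophil-like cells with a median of 723 UMIs per cell in Flox+RI against 1812.5 in the library labelled CKO+RI.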

Other observations

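The values in fibroblast-like cells and all tests below were chosen after the results were seen, except those of the windows of chromosome 15 and of chromosome 15 within single clusters. Fibroblast-like cells numbered 131 in the library labelled CKO+RI, 43 in Flox+RI and 237 in Flox+ICI, and Flox+RI is under the minimum of 50. In Flox+RI they had the contractile genes of myofibroblasts higher than in both other libraries and the genes of adventitial fibroblasts lower. All 8 measured contractile genes were lower in CKO+RI than in Flox+RI (median log2 ratio -3.01), and all 8 were higher in Flox+RI than in Flox+ICI (2.83). Tagln was at 119.6 against 1785 CPM in CKO+RI against Flox+RI, and Acta2 was 16.9-fold higher (12.9 to 22.5) in Flox+RI than in Flox+ICI. The extracellular matrix list had medians of -1.43 and 1.71, and the adventitial list 2.68 and -2.68, with Pi16 26.4-fold higher (12.7 to 66.3) in CKO+RI than in Flox+RI. The MHC class I and interferon gamma list had 1.07 and -1.52. Cxcl9, at 796 against 23.1 CPM, was 34.5-fold higher in CKO+RI (16.6 to 86.3), with a UMI in 9.92% of the cells against 9.30%. Genes of dissociation stress differed too (0.87 and -0.88). Cluster S4 held 90.7% of the class in Flox+RI, 20.6% in CKO+RI and 12.2% in Flox+ICI, but 0.333%, 0.322% and 0.297% of all kept cells, so the profile of the class went with fewer cells of its other clusters. No explanation was tested.

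The p53 and DNA damage response list lay lower in Flox+RI than in Flox+ICI in 4 classes, with median log2 ratios of -1.52 in endothelial, -0.74 in macrophage-like, -0.49 in CD8 T cell-like and -0.19 in tumour cells. CKO+RI over Flox+RI gave 1.05, 0.46, 0.00 and -0.18. Dissociation stress genes had -0.87, 0.62 and 0.37 in the first 3 classes of Flox+RI over Flox+ICI.

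In host cells, a set of genes had a median log2 ratio under -0.7 over at least 4 classes, each with at least 30 UMIs, in the library labelled CKO+RI over each Flox library, and another set was over 0.7. The lower set held Astl (median log2 ratio over classes -4.43 over Flox+RI and -3.80 over Flox+ICI), Pde4c (-3.99 and -3.30) and Nfe2l3 (-2.85 and -2.57). Its median in LLC tumour cell-like cells over Flox+RI was -0.74 (-0.85 to -0.65) and -0.48 (-0.61 to -0.42) with clusters 2 and 8 pooled in. Genes such as Hook2 (0.58) were not lower in that pool. The set also holds Pecam1, an endothelial marker, at -2.14 in the pool, and free host RNA in tumour droplets could carry a drop confined to host cells. The values therefore cannot decide whether an effect of Sfrp2 deletion would be confined to host cells or reach the tumour cells. Both stay open, untested. For the lower set, a ratio of median gene lengths of 1.19 (0.937 to 1.44) to other measured genes argues against gene length. Median lengths were 32.5 kb in the lower set, 12.1 kb in the higher set and 27.4 kb in the other genes. The length of the higher set was not tested, so a difference by gene length stays open there. Of the lower set, 12.1% (7.18 to 18.6) had a 4-fold more strongly expressed gene within 10 kb upstream on the same strand. For the others this was 1.82%, and for the higher set 2.30% (0.280 to 8.06). Read-through counted to a neighbour, as for Trim69 and Fbxl18, thus stays open for this part. The remaining 87.9% (81.4 to 92.8) argue against it for the whole lower set. A difference in how the library labelled CKO+RI was made or counted stays open, untested.

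MHC class I and interferon gamma genes were lower in Flox+RI than in Flox+ICI in tumour, macrophage-like and endothelial cells. A median of 0.70 (0.14 to 1.29) in alveolar macrophage-like cells argues against a shift of these transcripts over the whole library. Tumour cells without cluster 3 still had -1.05 (-3.36 to -0.83), which argues against cluster 3 alone. Less interferon gamma transcript in the tissue stays open as a hypothesis, since Ifng was at 2.64 CPM of all kept cells (2.31 to 3.01) in Flox+RI, 8.15 (7.48 to 8.87) in Flox+ICI and 6.96 (6.53 to 7.40) in CKO+RI, a level that also depends on the share of T and NK cells. Radiation, which the design names, stays open, untested.

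Chromosome 15 genes were higher in tumour cells of Flox+RI than of both other libraries (median log2 ratio 0.43 over CKO+RI). The highest of the medians over CKO+RI in macrophage-like, T cell-like, neutrophil-like and endothelial cells was 0.12 (0.05 to 0.16), which argues against a shift over the whole library. Over Flox+ICI macrophage-like cells had 0.13 (0.07 to 0.17), but neutrophil-like cells, at 0.25 (0.01 to 0.36), overlapped with the 0.36 (0.33 to 0.41) of tumour cells, so a shift in neutrophil-like cells stays open there. Of 10 windows of 10 Mb, 100% had a median over 0.1, which argues against a few strongly regulated genes. Within clusters 1, 4, 7 and 8, the last unnamed, the lowest median was 0.34 (0.28 to 0.41), so a tumour subpopulation with more copies of chromosome 15 stays open as a hypothesis, found and tested on the same data, and treatment as its cause was not tested.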
